A study of Mus musculus with 6 samples.

How the data were processed

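Poly-A RNA from whole retinas of 4-month-old C57BL/6J mice was sequenced in 6 libraries, 3 wild type and 3 Elovl2 C234W. Per the labels' protocols, strand-specific TruSeq libraries were made from poly-adenylated RNA. Per the series' design text, reads were mapped to mm10 with STAR (2.7.8a per the submitters' processing notes), and HOMER counted uniquely mapped tags in exons on the minus strand for 1 isoform per locus. The deposited values are estimated counts per gene, not normalized, per the file headers, in steps of 0.5. Between 28.3 and 32.1% of values per library were not whole, so counts were rounded to whole numbers for the count tests. The gene models carry RefSeq identifiers; their release is not given in the sources used here. Counting a single isoform with unique tags loses reads of genes with near-identical copies, and makes each value depend on which isoform was kept.

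Columns with the prefix WT were taken as wild type. The labels do not explain the prefix FS, and these 3 columns were taken as C234W by elimination, since the file header names 3 wild-type and 3 C234W directories. The direction of every fold change rests on this. The columns carry no sample number of the labels, so they served as replicates of a group without numbers. The number of sample columns left out was 0. Library totals in the header ran from 19426580 to 26672412 tags, of which 65.8 to 74.4% were counted in genes. Pairs of libraries were checked for duplicates by a chi-square of their counts over genes. The smallest value was 10.5 per degree of freedom, for WT2A and WT2B, so no pair was treated as 1 library.

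Of 25124 gene models, 5728 had 0 counts in the 6 libraries. Genes were kept by filterByExpr in edgeR (4.0.16, R 4.3.3), which left 14685. Libraries were scaled by TMM, and genotypes were compared by the quasi-likelihood test with robust dispersion and no covariate. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Values are TMM-scaled CPM, given as mean ± SD over 3 libraries, and log2 fold changes are C234W relative to wild type with their SE. Coordinates are those of the deposited table on mm10. The substituted codon was located in the GENCODE annotation of the same assembly.

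The text names Elovl2, the 10 genes higher and 10 genes lower with the largest log2 fold change among those past the threshold with a mean of at least 1 CPM and groups that did not overlap (sex-linked list members and symbols that are Gm plus digits or end in Rik left out), and in each gene list the 2 passing members with the smallest p or, where none passed, the member with the smallest p. Not every gene so named is reported here. This rule, the lists, the tests and the alternatives were fixed before the data were examined, apart from those said to be chosen later. There were 43 lists of pathways, complexes and cell type markers. Lists with at least 3 measured members, 41 in number, were tested with camera in limma (3.58.1) on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The directional p of fry tests whether a list's genes move one way on balance and its mixed p whether they move in either direction; 6 lists passed the former and 18 the latter.

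Alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter (1 CPM in 3 samples), DESeq2 (1.42.0), limma-voom, dispersion settings, an adjusted p under 0.01, a 2-fold minimum, and leaving out each library. Chosen after seeing the data were unrounded counts, summing libraries with the same number in their names, and removing from each library a loess trend of expression on transcript length, or on length and GC content, with a span of 0.3 (0.5 as another setting for length). GC content was matched for 99.4% of tested genes. Scaling to total counts shifted the median log2 fold change of all genes to 0.21, from 0.024 with TMM.

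The scripts were tested on simulated data for this comparison, on 14685 genes with 100 changed 2-fold and 100 changed 4-fold. edgeR recovered 42% of 2-fold and 90% of 4-fold changes, with 12 false calls among 144. DESeq2 recovered 63 and 91%, with 42 false among 196, and limma-voom 36 and 87%, with 7 false among 130. A shifted list passed camera and 0 other lists did. The simulated genes were drawn independently, so this does not test camera on correlated genes. In the data the estimated correlation reached 0.819, for the Müller glia stress and gliosis list. A length slope of 0.203 per doubling was reduced to 0.00487 by the offset.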

Results

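Retinas of 4-month-old C57BL/6J mice were compared by poly-A RNA sequencing between wild-type animals and animals carrying the C234W substitution in Elovl2, the elongase that lengthens long-chain polyunsaturated fatty acids on the way to docosahexaenoic acid, an abundant lipid of photoreceptor membranes. The comparison asks which transcripts differ in the retina when this enzyme carries the substitution. There were 3 libraries of each genotype. Wild-type libraries WT1A, WT2A and WT2B held 17343507.5, 18710329 and 14184093 counts in genes, and C234W libraries FS3A, FS3B and FS5A held 17179792, 19298613 and 15804645.5. The 6 libraries showed Xist and 0 counts over 4 Y-linked genes, the pattern of female tissue. The labels do not say that each library came from a separate animal, and WT2A and WT2B, like FS3A and FS3B, share a number in their names, so p-values measure only the spread between these samples. WT1A correlated more strongly with each C234W library (Pearson r 0.9689 with FS3A, 0.9642 with FS3B and 0.9718 with FS5A, on log2 CPM across genes, which are not independent replicates) than with WT2A (0.9609) or WT2B (0.9556).

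Elovl2 lies on chromosome 13 of mm10, from 41182382 to 41220403 on the minus strand (NM_019423). The codon named in the C234W substitution, of 292 in the coding sequence, is TGT in the reference and occupies positions 41186916 to 41186918, in exon 7 of 8. The transcript was measured at 138.7 ± 3.01 CPM (SD, n = 3) in wild type and 96.11 ± 17.9 CPM (SD, n = 3) in C234W, without overlap between the groups. The log2 fold change was -0.53 (SE 0.166) and did not pass the threshold (edgeR quasi-likelihood test, adjusted p = 0.0991). A point substitution need not alter the transcript level, so this value does not check the labels.

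In C234W retinas, genes of ribosomal proteins, of mitochondrial respiration and of rod photoreceptors were among those that fell, and most of the genes past the threshold were lower. Of 14685 genes tested, 267 changed, with 43 higher and 224 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05, 1796 genes were higher and 2011 lower. Of the 267, 85 changed at least 2-fold, with 31 higher and 54 lower, and the median absolute log2 fold change was 0.908. Across all tested genes, 29.1% had groups that did not overlap, against 10% expected on average over splits by chance. Genes vary together, so a single split can lie far from that average, and the share in the other splits was not computed. The 267 adjusted p-values lay between 0.0469 and 0.05, DESeq2 called 1717 genes, and scaling to total counts alone left 1 gene, Erdr1, with a split of 1 higher and 0 lower and 4417 genes at an unadjusted p under 0.05. Leaving out WT1A raised the count to 2771 (1339 higher and 1432 lower), whereas edgeR called 0 genes without WT2A, without WT2B or without FS3A (2384, 2224 and 2456 genes at an unadjusted p under 0.05), 1 without FS3B and 7 without FS5A. By settings chosen after seeing the data, 1 gene passed in edgeR with the transcript length trend of each library removed, and 0 passed with libraries of the same name number summed (3015 and 1844 genes at an unadjusted p under 0.05).

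Ribosomal protein genes formed the group with the smallest p by camera at the preset correlation; with an estimated correlation or by directional fry it was oxidative phosphorylation. Of 50 measured members, 23 fell, 0 rose and 27 did not pass the test, and 42 fell when adjusted over the list alone. The median log2 fold change was -0.90, and -0.51 with the length trend removed. Rplp2, a protein of the ribosomal stalk, fell from 80.09 ± 2.15 to 37.28 ± 2.92 CPM (SD, n = 3), a log2 fold change of -1.10 (SE 0.144, adjusted p = 0.0469), and -0.612 (SE 0.137, adjusted p = 0.107) with the length trend removed. Rps16, a protein of the small subunit, fell from 10.56 ± 0.518 to 3.196 ± 0.417 CPM (SD, n = 3). Ribosomal protein genes have many processed pseudogenes and only uniquely mapped tags were counted, so their absolute levels are uncertain. The camera test placed the list below other genes (adjusted p = 3.98e-24), and adjusted p = 0.652 with an estimated correlation.

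Subunits of the respiratory chain and ATP synthase were lower as well. Of 50 measured oxidative phosphorylation genes, 18 fell, 0 rose and 32 did not pass the test, and 38 fell when adjusted over the list alone. The median log2 fold change was -0.65, and -0.277 with the length trend removed. Among complex I subunits, Ndufa1 fell from 52.38 ± 5.97 to 26.23 ± 1.38 CPM and Ndufb9 from 192.7 ± 22.6 to 102.5 ± 2.57 CPM (SD, n = 3 each); with the length trend removed, their log2 fold changes went from -0.996 and -0.912 to -0.504 and -0.469 (adjusted p = 0.154 and 0.137). The list lay below other genes by camera (adjusted p = 9.29e-21), and adjusted p = 0.0946 with an estimated correlation. Beside both groups, transcript length moved with genotype: the fifth of genes with the shortest transcripts, up to 1671 bases, had a median log2 fold change of -0.34, and the fifth with the longest, from 4985 bases, had 0.28. The members' median lengths were 738 bases for ribosomal proteins and 890.5 bases for oxidative phosphorylation. Each member was also compared with genes matched on length and expression, a test chosen later. The median difference in log2 fold change was -0.315 for ribosomal proteins and -0.00407 for oxidative phosphorylation.

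**Figure D1:**
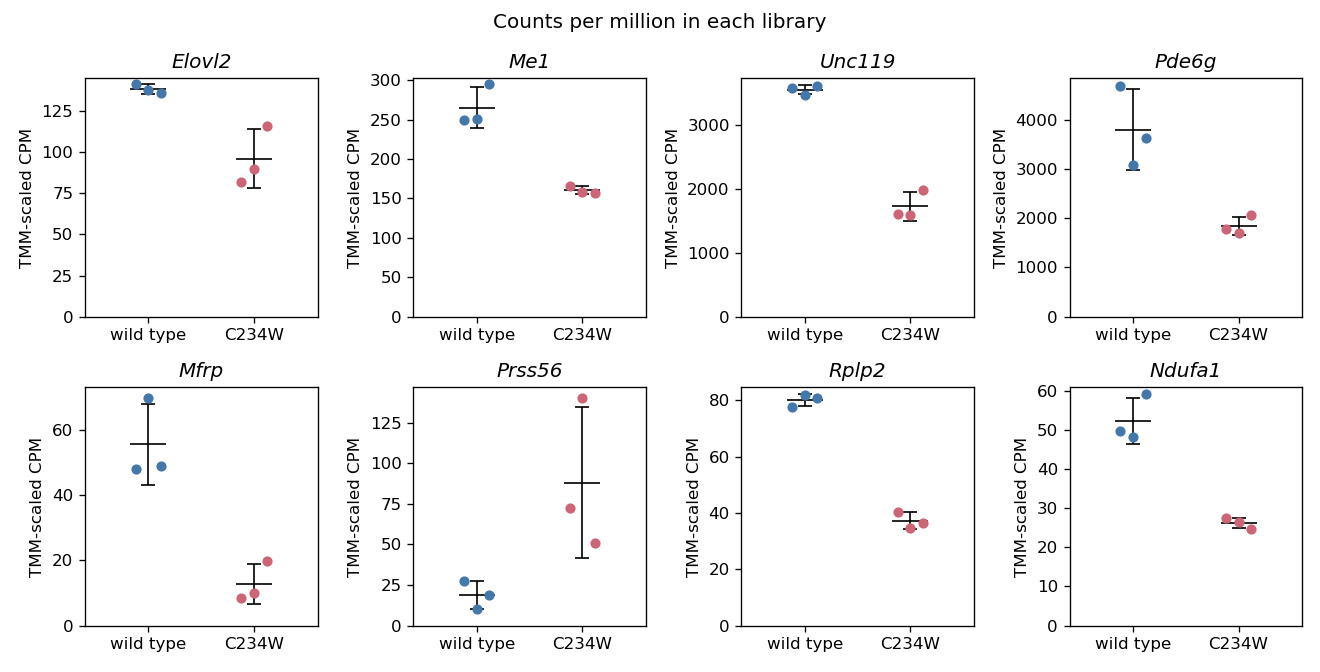
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each library, with points for libraries, horizontal bars for group means and error bars for SD (n = 3). Elovl2 averaged 138.7 CPM in wild type and 96.11 in C234W, and Prss56 was the gene shown that was higher in C234W, at 18.88 against 87.97 CPM.

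Rod genes fell in part. Among 34 rod phototransduction and outer segment genes, 3 fell, 0 rose and 31 did not pass the test, and 10 fell when adjusted over the list alone. Unc119, which chaperones acylated transducin, fell from 3548 ± 72.1 to 1725 ± 223 CPM (SD, n = 3), a log2 fold change of -1.04 (SE 0.18, adjusted p = 0.0469). Guca1a, a calcium sensor of photoreceptor guanylate cyclase, fell from 2314 ± 306 to 1170 ± 173 CPM, and Pde6g, the inhibitory subunit of rod phosphodiesterase, from 3808 ± 823 to 1849 ± 187 CPM (SD, n = 3 each). Of 12 rod markers 1 fell (Pde6g), and 5 fell when adjusted over the list alone. The camera adjusted p was 0.00193 for the phototransduction list and 0.000478 for the markers, and adjusted p = 0.826 and 0.652 with an estimated correlation. Without WT1A the phototransduction list did not pass (adjusted p = 0.77); its mean deviation was 0.625 in WT1A, -0.106 and -0.0348 in WT2A and WT2B, and -0.148, -0.36 and 0.023 in FS3A, FS3B and FS5A. In the list of 12 cone markers, 1 gene fell, Pde6h, the inhibitory subunit of cone phosphodiesterase, from 249.9 ± 68 to 99.98 ± 12.8 CPM (SD, n = 3), and the list did not pass (camera adjusted p = 0.587). With the length trend removed, the log2 fold changes of Guca1a and Pde6h went from -0.984 and -1.322 to -0.631 and -0.84 (adjusted p = 0.144 and 0.112).

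Among lipid genes, Me1, which makes NADPH used in fatty acid synthesis, fell from 265 ± 26.2 to 160.5 ± 4.98 CPM (SD, n = 3), a log2 fold change of -0.72 (SE 0.145, adjusted p = 0.0475). It was the 1 of 18 measured fatty acid and triglyceride synthesis genes to pass, and 3 passed when adjusted over the list alone. None of 34 genes of polyunsaturated fatty acid elongation, desaturation and handling passed in edgeR, by either adjustment, with 9 at an unadjusted p under 0.05 and 2 called by DESeq2. Over all tested genes, 3807 of 14685 were at an unadjusted p under 0.05, a share like that of these 34. Elovl4, the elongase of very long-chain fatty acids, chosen after its values were seen, had a log2 fold change of -0.56 (SE 0.156, adjusted p = 0.0789). Of 25 cholesterol synthesis genes and 30 genes of fatty acid oxidation and PPAR targets, 0 passed by edgeR, with 3 and 5 at an unadjusted p under 0.05 and 1 and 0 called by DESeq2. Camera, which tests a shift in one direction, gave adjusted p = 0.952, 0.879, 0.744 and 0.463 for the elongation, cholesterol, synthesis and oxidation lists. By the mixed fry test, which 18 lists passed, these were 0.0428, 0.344, 0.0229 and 0.126 in the same order.

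Among the 10 largest falls, Mfrp and C1qtnf5 share one locus on chromosome 9 (44101770 to 44109187) and nearly the same counts, so they were taken as 1 signal. Mfrp, a membrane frizzled-related protein needed for normal eye growth, fell from 55.69 ± 12.4 to 12.79 ± 6.19 CPM (SD, n = 3), a log2 fold change of -2.13 (SE 0.323, adjusted p = 0.0469). Ubtd1 fell from 226.6 ± 61.3 to 74.73 ± 12.3 CPM and Nfkbil1 from 39.77 ± 9.67 to 14.57 ± 2.91 CPM (SD, n = 3 each). The other falls were of genes at 10.56 CPM or less in wild type: Rps16, the muscle troponin Tnnc2 (-3.41 on the log2 scale), the transcription factor Foxf1 (-2.55), Nupr1l (-2.15), the zinc transporter Slc39a4 (-1.88) and the myelin-associated Ermn (-1.61). Without WT2A, without WT2B or without FS3A, none of the 20 genes of largest change passed in edgeR; 1 passed without FS3B and 3 without FS5A.

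The largest rise was that of Erdr1, which the gene models place on chromosome Y (90785442 to 90816465), within a region shared with chromosome X. Only uniquely mapped tags were counted, so tags that match both chromosomes would be lost and the absolute level of Erdr1 is uncertain. Erdr1 had 4 rounded counts over the wild-type libraries and 227 over the C234W libraries, a ratio of 48.1 (95% exact interval 18.5 to 178, for counting error only). Mid1, a ubiquitin ligase gene on chromosome X (169879619 to 169990797), rose from 17.04 ± 4.06 to 61.81 ± 25.2 CPM (SD, n = 3). Whether the rise of Mid1 is independent of that of Erdr1 was not tested. Prss56, a serine protease gene linked to eye size, rose from 18.88 ± 8.65 to 87.97 ± 46.6 CPM (SD, n = 3), a log2 fold change of 2.23 (SE 0.433, adjusted p = 0.0475). The remaining rises were of genes below 3 CPM in wild type: Cyyr1 (3.67 on the log2 scale), Csf2rb2 (2.69), the amino acid transporter Slc16a10 (2.40), the growth factor binding protein Igfbp3 (2.08), the betaine and GABA transporter Slc6a12 (1.91), the xanthine dehydrogenase Xdh (1.88) and the basement membrane protein Fras1 (1.62).

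In splits of the 6 libraries into 3 and 3 other than by genotype, 9 to 20 lists passed camera at the preset correlation. The number of passing lists thus does not set the genotypes apart. Of 41 lists tested by camera, 14 passed by genotype, with 4 higher and 10 lower in C234W, and 0 passed with an estimated correlation. The higher ones were Müller glia stress and gliosis, bipolar cell markers, extracellular matrix and vascular endothelium (camera adjusted p = 0.00104, 0.00339, 0.00361 and 0.00909, and adjusted p = 0.826, 0.652, 0.362 and 0.652 with an estimated correlation). In the gliosis list 1 of 30 genes rose, the endothelin receptor Ednrb, from 3.568 ± 1.07 to 11.03 ± 3.07 CPM (SD, n = 3). The gliosis list's mean deviation was 1.49 in FS3A and 0.897 in FS3B but -0.891 in FS5A, and 0.46, -1.05 and -0.9 in WT1A, WT2A and WT2B. The endothelium list did not pass without WT1A (adjusted p = 0.28); its mean deviation was -0.885 in WT1A, against 0.107 and -0.114 in WT2A and WT2B and 0.395, 0.326 and 0.171 in FS3A, FS3B and FS5A. None of 14 bipolar, 33 matrix and 12 endothelial genes passed over all genes in edgeR, while 6, 0 and 4 passed when adjusted over the list alone. DESeq2 called 6, 5 and 4 of them, and 7, 8 and 4 were at an unadjusted p under 0.05. The share over all genes was 3807 of 14685, so the matrix count was near it. The smallest p in these lists belonged to Isl1, a bipolar transcription factor (31.64 ± 0.535 against 51.51 ± 4.16 CPM, SD, n = 3, adjusted p = 0.0505), Fn1, fibronectin (adjusted p = 0.058), and Esam, an endothelial adhesion molecule (adjusted p = 0.0504). With the length trend removed, the matrix median log2 fold change went from 0.347 to 0.197, and its lower members from 6 to 13 of 33. The endothelium median went from 0.563 to 0.383, gliosis from 1.03 to 0.958 and bipolar from 0.401 to 0.458. The matrix list then passed at camera adjusted p = 0.0372. Fn1 went from 0.866 to 0.545 (edgeR adjusted p = 0.177).

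**Figure D2:**
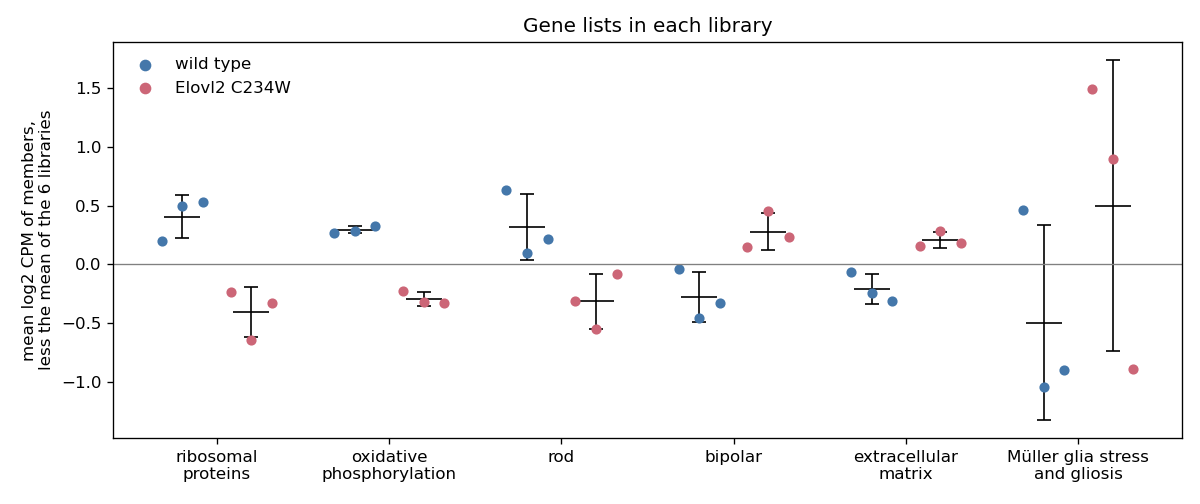
Mean log2 CPM of the members of 6 gene lists in each library, less the mean of the 6 libraries (vertical axis, log2 units), with points for libraries and bars for group means and SD (n = 3). The groups separate for ribosomal proteins, oxidative phosphorylation, rod markers, bipolar markers and extracellular matrix, while in the gliosis list FS5A lies at -0.891, below WT1A at 0.46.

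The remaining lower lists were erythrocyte markers, replication-dependent histones, lysosome and autophagy, oxidative stress defence, skeletal muscle and Müller glia markers (camera adjusted p = 0.00104, 0.0142, 0.0193, 0.0287, 0.0294 and 0.0319, and adjusted p = 0.652, 0.583, 0.826, 0.668, 0.583 and 0.826 with an estimated correlation). In the lysosome and autophagy list 2 of 32 genes fell, the autophagosome proteins Map1lc3b (207.6 ± 12.3 to 124.4 ± 8.33 CPM) and Map1lc3a (178.4 ± 28.2 to 98.84 ± 11.7 CPM; SD, n = 3 each); with the length trend removed, the log2 fold change of Map1lc3a went from -0.852 to -0.543 (adjusted p = 0.133). None of 7 erythrocyte, 7 histone, 31 oxidative stress, 5 muscle and 14 Müller glia genes passed over all genes in edgeR, and 6, 3, 7, 2 and 4 passed when adjusted over the list alone. DESeq2 called 6, 1, 7, 1 and 4 of them, and 6, 4, 8, 3 and 7 were at an unadjusted p under 0.05. The share over all genes was 3807 of 14685, so the oxidative stress count was near it. The smallest p among them belonged to Hbb-b1 (adjusted p = 0.064), Hist1h2bc (0.064), Prdx5 (0.0504), Acta1 (0.0745) and Rlbp1 (0.0547). With the length trend removed, the histone, oxidative stress, muscle and Müller glia lists did not pass (adjusted p = 0.296, 0.567, 0.104 and 0.0814). The oxidative stress list also did not pass without WT1A or without FS5A (0.177 and 0.157), the lysosome list without WT1A, FS3A or FS5A (0.118, 0.134 and 0.0651), the Müller glia list without WT2B or FS5A (0.0956 and 0.232) and the muscle list without FS3B (0.102). The haemoglobin genes are near-identical copies whose tags cannot be assigned with certainty.

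Another 27 lists did not pass camera, with adjusted p from 0.0576 for retinal ganglion cell markers to 0.996 for astrocyte markers. At the preset correlation, some of them passed with 1 library left out: ganglion cell markers, lower, without WT1A or FS3B (adjusted p = 0.00196 and 0.00834), circadian clock and amacrine markers, lower, without WT1A (0.0436 and 0.038), visual cycle, lower, without WT2A or WT2B (0.0406 and 0.00316), pigment epithelium, lower, without WT2B (0.00549), and complement, interferon and inflammation, higher, without FS5A (0.0168, 0.0117 and 0.000154). Besides the cone and lipid lists above, these were complement, visual cycle, unfolded protein and integrated stress response, interferon response, inflammation and cytokines, immediate early genes, circadian clock, synaptic transmission, glycolysis and lactate, apoptosis and p53 targets, ageing and senescence, and markers of amacrine cells, horizontal cells, microglia and macrophages, pericytes and smooth muscle, pigment epithelium, ciliary body and iris, cornea and conjunctiva, optic nerve oligodendrocytes and leukocytes. In the ageing list Igfbp3 rose, and Ermn fell in both the pigment epithelium and the oligodendrocyte lists. Pigment epithelium markers had a mean deviation of 1.28 in WT1A and between -0.656 and 0.091 in the other libraries. Sex-linked genes and lens markers had 1 measured member each, Xist and Crybb3, and were not tested as lists in the main fit. Lens markers had enough measured members without WT2A, FS3A or FS3B and did not pass (camera adjusted p = 0.0971, 0.379 and 0.271).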

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

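The length-trend, unrounded and summed-library settings were chosen after seeing the data. The 267 changed genes (43 higher, 224 lower) became 1717 in DESeq2 (685 higher, 1032 lower), 1 with total-count scaling (1 and 0), and 0 at an adjusted p under 0.01 (0 and 0; edgeR, 3807 genes at an unadjusted p under 0.05). With at least a 2-fold change there were 85 (54 lower). Without the low-count filter 85 genes were higher, and with legacy quasi-likelihood 27. Summing libraries of one name number left 0 (0 and 0, with 1844 at an unadjusted p under 0.05), in a fit with fewer samples. Removing the length trend, alone, with GC or with a wider span, left 1 (1 and 0). Apart from transcript length, treated below, the cause of these changes was not tested. Leaving out 1 library gave 0 to 2771 changed genes, 0 to 1339 higher and 0 to 1432 lower. The highest values came without WT1A and the lowest without WT2A, WT2B or FS3A, for lower genes also without FS3B. The 267 genes kept their direction in each setting that measured them. All 267 had groups that did not overlap, so leaving out or summing libraries could hardly reverse them, and this is no sign of robustness. DESeq2 shared all 267 calls and limma-voom 235. The remaining settings gave 200 to 350 changed genes.

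Elovl2 stayed lower and short of the threshold in each setting, from -0.69 to -0.35 (adjusted p from 0.0629 to 0.447); without 1 library it ranged from -0.69 to -0.42. The 14 lists became 0 with an estimated correlation and 6 with the directional fry test, whose cause was not tested, became 18 with the mixed fry test, and were 13 to 16 in the other camera settings, 13 to 15 without 1 library, though not always the same lists. With the length trend removed 4 were lost and 4 others passed (interferon, inflammation, circadian clock and synaptic lists). Without WT1A 4 were lost and 3 others passed. Total-count scaling lost 0, and visual cycle and ganglion cell markers passed as well, both lower (camera adjusted p = 0.0346 and 0.0247). Of the 14, 8 passed without each library in turn and 7 of these also with the length trend removed. For other named genes, 864 values across settings stayed on their side of the threshold, 325 lost it, 51 gained it and 0 reversed. These genes were chosen for a large change or a small p in the same libraries, so a reversal was unlikely. No paired analysis was possible because the data columns carry no sample numbers of the labels. The effect of depth was not tested; Erdr1, the largest rise, had 4 rounded counts over the wild-type libraries.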

Other observations

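All tests in this part except the 10 Mb test and the count of lists over other splits were chosen after the result was seen, and the use of an interval in the 10 Mb test was added after its result was seen.

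Several genes of the stress and cytokine lists, chosen after their values were seen, varied widely within genotypes. Gfap, the glial intermediate filament, was at 46.76, 25.3 and 20.38 CPM in WT1A, WT2A and WT2B and at 248.4, 99.41 and 26.46 CPM in FS3A, FS3B and FS5A (adjusted p = 0.142). Serpina3n, an acute-phase protease inhibitor, was at 23.11, 8.558 and 6.989 CPM and at 80.37, 111.1 and 12.19 CPM (adjusted p = 0.119), and the chemokine Cxcl1 at 3.321, 0.323 and 0.1471 CPM and at 25.62, 12.33 and 0.2439 CPM (adjusted p = 0.166). Cxcl12 had groups that did not overlap, at 5.216 ± 2.67 and 15.5 ± 1.83 CPM (SD, n = 3; adjusted p = 0.0531).

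Of the 10 splits of the 6 libraries into 3 and 3, the genotype split gave 267 changed genes and the highest of the others 12; the 224 lower and 43 higher genes were each set against a highest other count of 12 in one direction. In each case 1 split, the real one, gave as many. For lists, 5 splits, the real one among them, gave 14 or more and the highest other gave 20. The count of lists thus did not set the genotype split apart. With 10 splits no share under 0.05 can be reached.

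The 267 genes set apart short from long transcripts. The median length was 1110 bases for those lower and 4745 for those higher, against 3020 for tested genes, and the length slope of each library separated the genotypes (-0.0692, -0.0978 and -0.113 in wild type, 0.0691, 0.113 and 0.0972 in C234W, log2 per doubling; exact two-sided permutation p = 0.1, the smallest possible). As a test of transcript length bias between libraries, the length trend removed from each library left 1 gene, Erdr1, but the 267 kept a median of 72% of their log2 fold change, the median SE went from 0.163 to 0.159, and 258 stayed at an unadjusted p under 0.05. Of all tested genes, those at an unadjusted p under 0.05 went from 3807 to 3015, and the adjusted p-values of the 267 then ran from 0.0338 to 0.371. Transcript length bias between libraries may account for part of the pattern; as the slopes follow genotype, it cannot be told apart from a shift of short transcripts in the retina.

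Ribosomal protein genes were compared with 10 genes each, matched on length and expression. The median difference in log2 fold change was -0.315 (bootstrap interval over member genes -0.355 to -0.217), and 45 of 50 lay below their matches. In these libraries, their fall was thus larger than that of genes of like length and expression. The bootstrap intervals given here resample genes, which are not independent (estimated correlation 0.659 for ribosomal proteins). They do not measure the spread between libraries. The list median less that of all genes (closest to 0 at -0.924 over 4 scalings) says nothing of scaling, which shifts every gene alike. For oxidative phosphorylation the matched difference was -0.00407 (-0.0975 to 0.0661), and 25 of 50 lay below their matches. In these libraries, their fall was thus no larger than that of genes of like length and expression. With the length trend removed, however, the list median went from -0.651 to -0.277. The list then still passed camera at the preset correlation (adjusted p = 2.42e-06). With an estimated correlation and the trend kept, the camera adjusted p was 0.0946. Length bias and a change of these genes therefore cannot be told apart. Lower ribosomal protein transcripts beyond the length trend may be a difference between genotypes, a hypothesis that tag loss to pseudogenes, not tested, leaves open.

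Mfrp with C1qtnf5 fell while Prss56 rose, and the log2 fold changes without WT1A were -2.23 (adjusted p = 0.0128) and 2.62. Over the 6 libraries the 16 pigment epithelium markers had a median log2 fold change of -0.831. Without WT1A, the library richest in them, it was 0.227 (lowest -1.56, highest 2.28). As WT1A was left out for being richest, this cannot decide whether C234W libraries held less pigment epithelium. The markers' mean deviation was 1.28, -0.117 and -0.656 in WT1A, WT2A and WT2B, and -0.619, 0.0251 and 0.091 in FS3A, FS3B and FS5A. Mfrp was at 48.02, 69.97 and 49.07 CPM and at 8.431, 10.05 and 19.88 CPM in the same order. The 8 ciliary body and iris markers had a median of 0.194 and a lowest of -0.907, with an estimated correlation of -0.0359. As these markers did not vary together, they cannot decide whether C234W libraries held less of this tissue. With the length trend removed Mfrp was at -2.3 (SE 0.334, from -2.13, SE 0.323); its call ended (adjusted p = 0.0974) while its fold did not shrink and the genes at an unadjusted p under 0.05 went from 3807 to 3015. A change in Mfrp expression with the Elovl2 genotype is a hypothesis these tests leave open, and a linked or strain variant was not tested at this locus.

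If variants linked to the edited locus altered nearby genes, genes within 10 Mb of Elovl2 should pass more often. Of 95 such genes 24 were at an unadjusted p under 0.05, or 25.3% (exact 95% interval 16.9 to 35.2%), against 25.9% of 14589 others (two-sided Fisher's exact p = 1). The interval reaches 1.36 times the share elsewhere, so a modest excess is not excluded. Of the 267 genes, 2 lay in this window, Fars2 and Dtnbp1, named after their values were seen.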
